A study of Mus musculus with 4 samples.

How the data were processed

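The 4 droplet libraries came from mouse embryos on a C57BL/6 background, 1 per group: Tomato+ and YFP+ cells of the N123 experiment and Tomato+ and YFP+ cells of the Rbpj experiment. Per the labels, the cells were sorted by FACS and libraries were made with a 10x Chromium 3′ kit. The numbers of embryos pooled and the deleted exons are not given in the sources used here. The deposited values are counts, whole-number UMIs per gene and barcode that were not normalised, in filtered matrices made with Cell Ranger 7.1.0 for N123 and Cell Ranger 6.1.2 for Rbpj, per the file headers. The submitters' processing notes name Cell Ranger 6.1.2, Seurat, GRCm38 and mm10, whereas the deposited gene models carry GRCm39 in their header and hold 21887 features, 3 of them transgenes, and all coordinates printed are of GRCm39 as given there. Whether reads in introns were counted is not given in the sources used here, and since the counting version differs between experiments, levels were compared within an experiment only. The other deposited values, of the unit other, are gene positions, feature names and barcodes, taken as they stand. Where several features share a symbol (19 symbols), each was kept apart.

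Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. In N123 KO, N123 WT, Rbpj KO and Rbpj WT, 174, 473, 642 and 1428 barcodes fell below the UMI or gene minimum, 155, 301, 549 and 433 more lay above the mitochondrial limit, and 10447, 10061, 11809 and 19011 passed. The lowest deposited barcode held 505, 500, 502 and 500 UMIs. Doublets were scored per library with Scrublet as in scanpy, and the highest scores were removed at 0.8% per 1000 barcodes, which took 873, 810, 1116 and 2891 barcodes (8.36%, 8.05%, 9.45% and 15.2%). Doublets that escape this step remain possible, so the share of UMIs in 1 cell is given where a single cell holds much of a gene in the library with the higher level. Kept cells had medians of 3934, 3809, 3261 and 2527 genes and of 2.78%, 2.31%, 4.64% and 3.72% mitochondrial UMIs.

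Counts were scaled to 10000 UMIs per cell and log-transformed, 3000 variable genes were ranked across libraries, and 50 principal components, a graph of the 15 nearest neighbours and Leiden clustering at resolution 1.0 gave 55 clusters. Notch1, Notch2, Notch3, Rbpj, the Notch target list and sex-linked, mitochondrial, ribosomal protein, haemoglobin and reporter genes were left out of clustering. No integration was applied. Connective tissue clusters separated by experiment while other classes shared clusters, with chondrocyte-like cells mostly in cluster 1 for N123 and cluster 19 for Rbpj and mesenchyme-like cells in cluster 22 and cluster 0. These class names need not cover like cells in both experiments. A cluster was named from 27 fixed marker classes with 241 markers when at least 3 markers were detected in at least 10% of its cells with a log2 fold above 1, the mean marker log2 fold was at least 0.75 and a marker was among its top 20 genes. It stayed unnamed when another class had more markers among its top 10 genes. Folds used a pseudocount of 10 CPM and the other cells of the same experiment. These naming thresholds were tightened after clusters had been seen, and leave 57.3%, 37.4%, 36.0% and 26.4% of N123 KO, N123 WT, Rbpj KO and Rbpj WT cells in 14 clusters with no name.

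Shares are percentages of kept cells with exact Clopper-Pearson intervals, computed here from the deposited counts. Expression was compared as UMIs summed over the cells of a class in a library, as the log2 ratio of KO to WT CPM (UMIs scaled to the library total) with a pseudocount of 5 CPM, in classes with at least 50 cells in both libraries. Because of the pseudocount, ratios of genes near 5 CPM understate a difference. The standardised log2 ratio is the mean over the 5 classes with at least 100 cells in all 4 libraries. Confidence is 95%, a share of 0 is given with the limit that 3 counts set, and all intervals cover counting error only. With 1 library per group no test across replicates exists, so no p-value or number of changed genes is given. For each of 28 fixed gene lists the median log2 ratio of members with at least 20 UMIs was set among 10000 random lists of the same size matched on mean expression, which describes these libraries only. The correlation between experiments used genes with a mean of at least 20 CPM.

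Genes named in the text follow a rule with 4 parts. Notch1, Notch2, Notch3, Rbpj, Hes1, Hes5, Hey1, Hey2, Heyl and Nrarp are always named. The 8 highest and 8 lowest standardised ratios are named among genes with at least 20 CPM on average in either library and at least 50 UMIs that lie on 1 side of 0 in at least 75% of the classes. The 3 highest and 3 lowest ratios with at least 50 UMIs are named in neural progenitor-, neuron-, endothelial-, mural- and skeletal muscle-like cells. Mitochondrial, ribosomal protein, haemoglobin, Xist, Tsix, Y-linked and reporter genes and unnamed gene models were left out of these. Of each list described, 2 to 4 members with the largest and smallest ratio are named. Some list members that this would name are not reported here. PhiYFP, Hba-x, the Y-linked genes, genes that lead a cluster, Notch2 and Ulk4 in the split by PhiYFP, and list medians within mural-like, neuron-like and neural progenitor-like clusters lie outside the rule and were chosen after their values were seen. The comparisons, cell filter, markers, lists, naming rule for genes and the alternatives listed below, apart from those said to be added later, were fixed before the data were examined.

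The method was tested on simulated data drawn from the class means and library sizes with 50 genes each at log2 changes of −2, −1, 1 and 2. For N123, with 6856 genes, the median estimates were −1.68, −0.90, 0.91 and 1.87, and for Rbpj, with 6321 genes, −1.65, −0.85, 0.92 and 1.88, with 100.0% of genes on the right side of 0 at each size. A list planted at −1 lay below every random list in both, and an unchanged list at percentile 11.4 for N123 and 32.3 for Rbpj. The simulated counts carried counting error only, so this does not measure differences between libraries that have other sources. The median of the unchanged genes was subtracted from the median estimates given here, which was not done for the reported ratios.

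Alternatives were a stricter filter of 2000 UMIs and 1000 genes, at most 5% mitochondrial UMIs, no doublet removal (54 clusters), Leiden resolutions of 0.5 (33 clusters) and 2.0 (82 clusters), classes from the highest marker score of each cell, cells thinned to 2000 UMIs (leaving out 27, 157, 46 and 1585 cells), median-of-ratios scaling, a pseudocount of 1 CPM, no filter on low counts, the median over classes or the sum over all kept cells in place of the mean, and a minimum of 100 CPM for the correlation. Leaving out 9 clusters that came to over 90% from 1 Rbpj library, and leaving out Rbpj KO cells with a PhiYFP UMI, were added after the data were seen. Versions were python 3.11.15, numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9.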

Results

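Mouse embryos that carried a tamoxifen-inducible Flp recombinase and a mosaic allele were used, so that recombined cells of 1 embryo were labelled either with Tomato, together with a gene deletion, or with YFP, without it. In the first experiment the deletion covered the receptors Notch1, Notch2 and Notch3 (N123) and was induced at embryonic day E7.5. In the other experiment it covered Rbpj, the DNA-binding protein through which Notch receptors act on transcription, and was induced at E9.5. Embryos were collected at E13.5, dead cells were excluded with DAPI, and Tomato+ and YFP+ cells were sorted and sequenced as droplet 3′ single-cell libraries. There were 4 libraries, 1 per group: N123 KO (Tomato+), N123 WT (YFP+), Rbpj KO (Tomato+) and Rbpj WT (YFP+). In that order the libraries held 10776, 10835, 13000 and 20872 barcodes, of which 9574, 9251, 10693 and 16120 were kept, with medians of 13286.5, 12408, 10533 and 6765 UMIs per kept cell. The deposited libraries held 174767803, 158632769, 160921269 and 170134852 UMIs in all. With 1 library per group no difference below has a replicate or a test. Intervals are exact 95% intervals (Poisson for counts, Clopper-Pearson for shares) or come from 200 Poisson redraws for mean log2 ratios, and all cover counting error only. KO and WT libraries differ in the fluorophore sorted as well as in the deletion, and the experiments differ in induction day as well as in the gene deleted.

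The 45638 kept cells formed 55 clusters, of which 41 were named from fixed markers and made up 19 classes. Clusters without a name held 57.3% of N123 KO, 37.4% of N123 WT, 36.0% of Rbpj KO and 26.4% of Rbpj WT cells, so the share of a class is a share of all kept cells, not of the named ones. The most numerous unnamed clusters were led by cell division and histone genes (clusters 2 and 6), by Alx1, Barx1 and Runx2 (clusters 3 and 5) or by limb Hox genes such as Hoxd11 and Hoxa10 (clusters 4 and 8). With 1 library per group, a cluster mostly of 1 library may be that library, not a type.

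The targeted genes were read in every library first, since a 3′ tag need not cover a deleted part and the labels do not name that part. In the N123 experiment Notch1 (ENSMUSG00000026923, GRCm39 chromosome 2, 26347915 to 26406675, minus strand) had 4.52 CPM (UMIs scaled to the library total; 4.19 to 4.88) in KO cells and 30.6 CPM (29.6 to 31.5) in WT cells, so that KO cells held 14.8% of the WT level. Notch3 (ENSMUSG00000038146, chromosome 17, 32339794 to 32385826, minus strand) had 15.9 CPM in KO and 26.3 CPM in WT cells, or 60.3% of the WT level. Notch2 (ENSMUSG00000027878, chromosome 3, 97920843 to 98057677, plus strand) had 46.0 CPM (44.9 to 47.1) in KO and 45.9 CPM (44.8 to 47.0) in WT cells, so its tags show no difference over all cells. Within classes KO cells held 32.5% of the WT level of Notch2 in endothelial-like (13 against 19 UMIs), 79.7% in mesenchyme-like, 83.2% in mural-like, 90.8% in chondrocyte-like and 134% in neuron-like cells (8 against 62 UMIs). Rbpj, which was not targeted there, had 113 CPM in KO and 130.4 CPM in WT cells. In the Rbpj experiment Rbpj (ENSMUSG00000039191, chromosome 5, 53623494 to 53814704, plus strand) had 42.4 CPM (41.3 to 43.5) in KO and 81.5 CPM (80.0 to 82.9) in WT cells, so that KO cells held 52.0% of the WT level. Notch2 was also lower in Rbpj KO, with 26.9 against 52.5 CPM, while Notch1 had 37.8 against 52.9 CPM and Notch3 14.2 against 14.5 CPM.

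The level of the targeted gene in KO cells differed between classes. Notch1 in N123 KO was 8.97% of the WT level in neuron-like (2 against 231 UMIs; KO 0.16 to 4.795 CPM), 12.1% in chondrocyte-like, 15.6% in skeletal muscle-like, 24.5% in mural-like, 36.6% in endothelial-like and 43.4% in neural progenitor-like cells. In neural progenitor-like cells this was 57.0 CPM (44.5 to 72.1) in KO against 131 CPM (125 to 137) in WT. Rbpj in Rbpj KO was 39.1% of the WT level in mesenchyme-like, 45.5% in chondrocyte-like, 49.9% in mural-like, 57.6% in endothelial-like, 61.4% in skeletal muscle-like, 64.2% in neuron-like and 82.9% in neural progenitor-like cells. As a mean over the 5 classes with at least 100 cells in every library (chondrocyte-, mesenchyme-, mural-, neuron- and skeletal muscle-like), called the standardised log2 ratio below, Notch1 was at −1.45 (−1.61 to −1.32), Notch3 at −0.58 (−0.74 to −0.46), Notch2 at −0.12 and Rbpj at 0.05 in N123. In the Rbpj experiment the standardised ratio was −0.90 (−0.98 to −0.83) for Rbpj, −0.84 (−0.98 to −0.72) for Notch2, −0.07 for Notch1 and −0.16 for Notch3. Without 9 clusters that came almost wholly from Rbpj WT, described below, Notch2 was at −0.54 and Notch1 at 0.05 there. Over the sum of all kept cells Notch2 in N123 turned to 0.0025 and Rbpj there to −0.20, and with cells thinned to 2000 UMIs it was at −0.34 and Notch3 in the Rbpj experiment at 0.11.

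**Figure D1:**
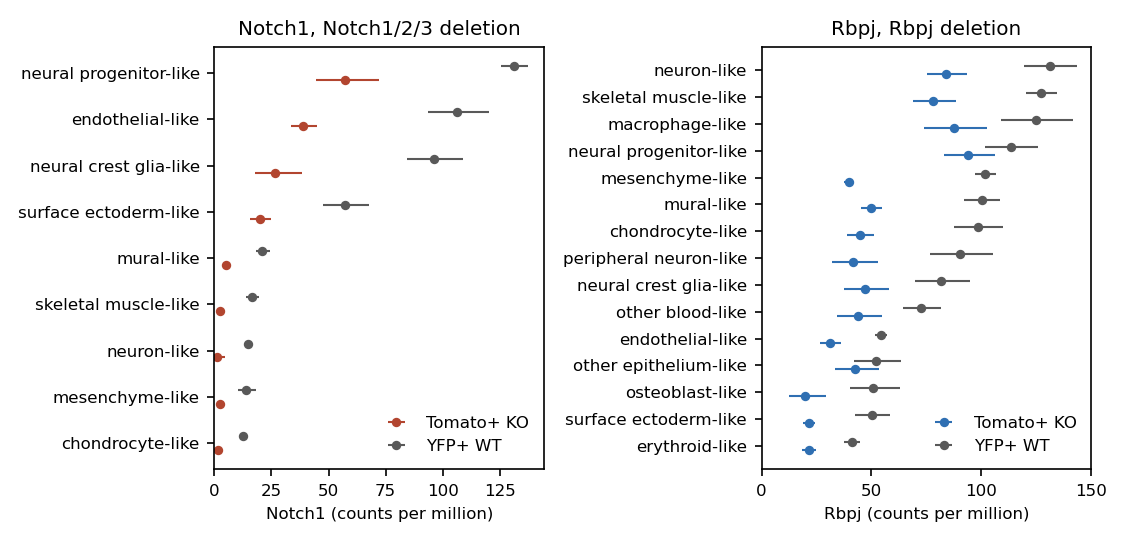
Notch1 in the N123 experiment and Rbpj in the Rbpj experiment (x axes, CPM) in each class with at least 50 cells in both libraries and 50 UMIs of the gene (y axes), with points for Tomato+ KO and YFP+ WT cells and exact Poisson intervals as lines (counting error only). Both genes lie lower in KO than in WT cells in each class drawn, with 57.0 against 131 CPM of Notch1 in neural progenitor-like cells.

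The N123 comparison asked which cell types hold Tomato+ cells, marked for deletion of the 3 receptors, and how such cells differ from YFP+ WT cells. Cells of the central nervous system were far scarcer among N123 KO cells. Neural progenitor-like cells made up 0.867% of N123 KO (0.691 to 1.07; 83 cells) and 12.3% of N123 WT (11.6 to 12.999; 1139 cells), a log2 ratio of −3.83 (−4.17 to −3.51). Neuron-like cells made up 1.35% (1.13 to 1.60; 129 cells) against 18.0% (17.2 to 18.8; 1662 cells), a log2 ratio of −3.74 (−4.01 to −3.48). Skeletal muscle-like cells were lower as well, at 1.32% against 3.52% (log2 −1.42, −1.73 to −1.12), and so were neural crest glia-like cells at 0.574% against 1.503% (−1.39, −1.86 to −0.93), macrophage-like cells at 0.188% against 0.562%, erythroid-like cells at 0.700% against 1.30% and other blood-like cells at 0.104% against 1.09%. With classes taken from the highest marker score the log2 ratios were −0.97 for muscle-, −0.41 for glia-, −0.78 for macrophage- and −0.34 for other blood-like cells (−3.39 by cluster). The ratio of erythroid-like cells was −0.18 at resolution 2.0 (−0.89 at 1.0). Peripheral neuron-like cells stood at 0.334% against 1.28% (log2 −1.93), which turned to 0.28 when each cell was given the class of its highest marker score.

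Several connective tissue and lining types made up a larger share of N123 KO. Endothelial-like cells were 2.11% of KO (1.83 to 2.42; 202 cells) and 0.832% of WT (0.657 to 1.04; 77 cells), a log2 ratio of 1.34 (0.96 to 1.74). Mesenchyme-like cells were 6.13% against 2.52% (log2 1.28), surface ectoderm-like cells 2.01% against 1.03% (0.97) and chondrocyte-like cells 19.4% against 11.7% (0.73). Chondrocyte-like cells of N123 lay mostly in cluster 1, led by C1qtnf3 and Cdh18 with Col9a3, Col2a1 and Cnmd among its first 10 genes. C1qtnf3, Igf1, Angptl1 and Fibin were among the first 10 genes of both cluster 1 and mesenchyme-like cluster 0. Col2a1 UMIs per 10000 UMIs in N123 KO and WT were 3.03 and 3.94 in cluster 1 and 1.57 and 4.29 in unnamed cluster 18. In Rbpj KO and WT they were 24.5 and 28.7 in cluster 19 and 0.895 and 1.12 in cluster 0, so the name chondrocyte-like covers unlike cells. Mesenchyme-like cells were at 0.60 at resolution 0.5. Chondrocyte-like cells were at 0.31 at resolution 2.0. Mural-like cells, named from genes of pericytes and smooth muscle, were 6.13% against 5.83%, with an interval of the log2 ratio that includes 0 (−0.10 to 0.24). Most of them are not vascular by their leading genes. Cluster 16, led by Actg2, Myh11 and Mylk with Tcf21 and Foxf1, held 59.1% of the class in KO and 51.2% in WT, cluster 23, led by Tcf21, Gucy1a1 and Foxf1 with Wnt2, held 28.1% and 34.5%, and cluster 26, led by Rgs5 with Abcc9 and Kcnj8, held 12.8% and 14.1%. Since shares add up to the whole, the scarcity of neural cells alone raises the share of every other type.

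**Figure D2:**
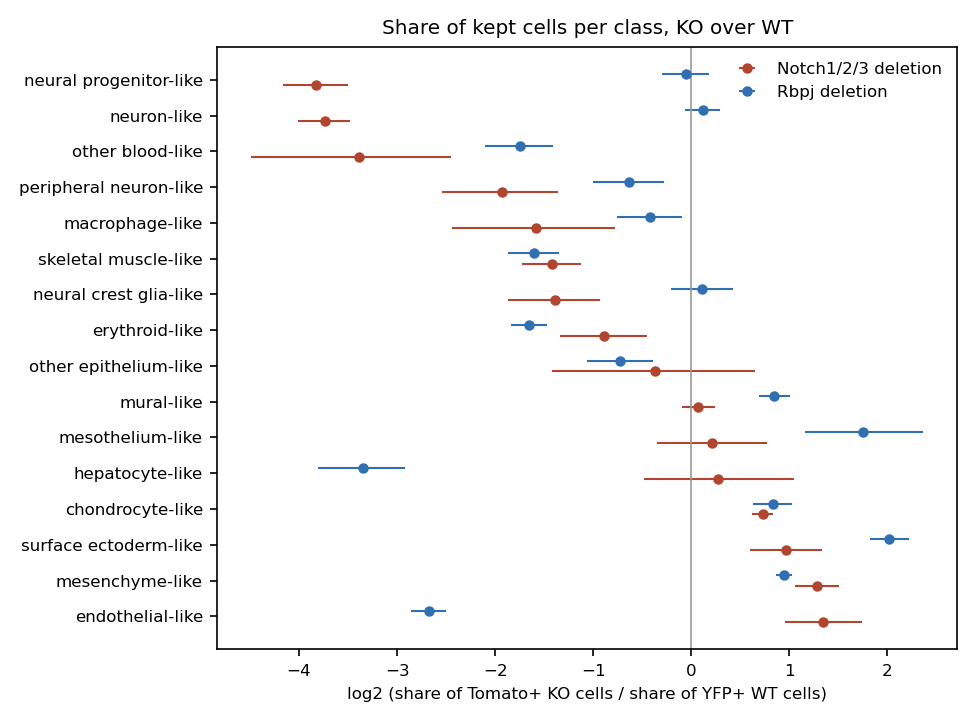
Log2 ratio of the KO to the WT share of kept cells for the classes drawn in the N123 and Rbpj experiments, with 95% intervals as lines (counting error only). Neural progenitor-like shares stand at −3.83 in N123 and −0.06 in Rbpj, and endothelial-like shares at 1.34 in N123 and −2.68 in Rbpj.

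Notch target genes had a median below 0 in N123 KO cells in each of the 9 classes in which the list could be measured. Of the 9 members of the fixed list, 8 had a standardised log2 ratio below 0, the list median was −0.54, and all 10000 matched random lists had a higher median, as a description of these libraries. Hes1, a repressor of neurogenic and myogenic factors, was at −0.71 (−0.84 to −0.60), Hey1 at −0.60 (−0.76 to −0.45), Heyl at −0.60, Hes5 at −0.58, Nrarp at −0.54 and Hey2 at −0.23. By class the median was −1.54 in neural crest glia-like cells, where Hes5 had 1 UMI in KO against 149 in WT, −0.92 in mural-like, −0.87 in skeletal muscle-like, −0.74 in neural progenitor-like, −0.48 in endothelial-like, −0.47 in surface ectoderm-like, −0.31 in neuron-like, −0.17 in mesenchyme-like and −0.14 in chondrocyte-like cells. Hes1 was at −1.74 in skeletal muscle-like, −1.26 in mural-like and −0.84 in chondrocyte-like cells. In neural progenitor-like cells Hes5 had 164.6 CPM in KO and 372 CPM in WT. The median over classes in place of the mean put the list at −0.26, and with cells thinned to 2000 UMIs its median was −0.19 in neural progenitor-like and −1.96 in mural-like cells.

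The few neural cells of N123 KO differed from WT in their neurogenic genes. In neural progenitor-like cells the proneural genes, the transcription factors and partners that start neurogenesis, had a median of −0.48 with 13 of 16 members lower, among them Eomes at −1.90 and Nhlh1 at −1.51, with Neurod4 at 1.21. In the same cells fibrillar matrix genes had a median of 0.97 and dissociation and stress genes of 0.83, and in cluster 12, the most numerous one of this class, the median doublet score was 0.069 in KO and 0.020 in WT. Neural progenitor genes had a median of −0.47 with 12 of 13 lower, from Ednrb at −1.004 and Fabp7 at −0.94 to Prom1 at 0.08. Neuron-like cells had all 16 proneural genes lower (median −0.78; Eomes −1.83), while neuronal differentiation genes had a median of 0.49 with 10 of 15 higher, led by the neurofilament genes Nefm at 1.94 and Nefl at 1.75, with Rbfox3 at −0.25. Without doublet removal the latter median was 0.29. Genes of S phase and of G2 and M phase had medians of −0.56 and −0.86 in neuron-like cells. Cluster 9 held 80.6% of these cells in KO and 66.4% in WT. Cluster 35, led by Neurod6 and Neurod2 with Tbr1, held 4 KO and 134 WT cells. Within cluster 9 the medians were −0.61 for proneural genes (16 of 16 lower), 0.47 for neuronal differentiation genes, −0.30 for S phase and 0.01 for G2 and M phase genes. The largest single ratios in these classes often rest on 1 cell. In neural progenitor-like cells Ttr was at 6.80 with 77.3% of its 838 KO UMIs in 1 cell, Hoxb13, a gene of the caudal end of the body axis, at 3.96 and Ifitm1 at 3.34, while Tfap2b was at −2.50 (7 against 769 UMIs), Helt at −2.25 (0 against 259 UMIs) and Cyp26b1 at −2.24 (9 against 736 UMIs). In neuron-like cells Atoh7 was at 4.25, Myl1 at 4.04 and Prph at 3.83, with 41.5%, 41.7% and 30.9% of the KO UMIs in 1 cell, and H1f5 was at −2.71, Sox6 at −2.40 and Top2a at −2.36. Without doublet removal H1f5 and Top2a turned to 0.25 and 0.27.

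Skeletal muscle-like cells of N123 KO held more transcripts of differentiated muscle, while progenitor genes went both ways. All 13 measured myogenic differentiation genes were higher (median 1.26, above every matched random list), with Acta1 at 2.04 and Myh3 at 1.91, which encode a sarcomeric actin and the embryonic myosin heavy chain, and Myod1 at 0.74 and Mymx at 0.66. Of the myogenic progenitor genes 4 of 8 were lower (median −0.44), with Msc at −2.20 and Pax7, the marker of muscle stem cells, at −1.79, and with Myf5 at 0.24 and Pax3 at 0.20, and with cells thinned to 2000 UMIs that median was −0.79. S phase genes had a median of −0.78 with 41 of 42 lower. Car3, an abundant enzyme of muscle fibres, had 669.6 CPM in KO and 54.9 CPM in WT (log2 3.49), Tnnt3 577 against 77.4 CPM (2.82), and Ankrd2 was at 2.75 (41.1% of its KO UMIs in 1 cell), while Fap was at −2.55 and Postn at −2.08. Different clusters made up most of this class. In KO 55.6% of the cells were in cluster 45, led by Mylpf, Myl1, Tnnc2, Acta1 and Myh3, and in WT 83.7% were in cluster 21, led by Msc, Myog, Tnnt1, Myod1 and Pax7. The lower share of the class in KO lay in cluster 21, at 0.564% of KO and 2.95% of WT cells (log2 −2.39). Cluster 45 was not scarcer, at 0.731% of KO and 0.562% of WT cells (0.38, −0.16 to 0.93).

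Mural-like and endothelial-like cells of N123 KO differed from WT in genes of pericytes and of arteries. In mural-like cells the pericyte list had a median of −0.75 with 8 of 9 members lower, among them Rgs5 at −1.50 and Vtn at −1.37, with Anpep at 0.06, while contractile genes stood at 0.11 (Myh11 0.68, Tagln −0.29). Within clusters 26, 16 and 23 pericyte genes had medians of −1.12, −0.43 and −0.56 and contractile genes of −1.28, 0.53 and 0.01, with 75 KO and 76 WT cells in cluster 26. The mural extremes were Pf4 at 1.89 (48.1% of its KO UMIs in 1 cell), Dkk1 at 1.46 and Ptprt at 1.32, and Car4 at −1.69, Heyl at −1.68 and Fabp7 at −1.61. In endothelial-like cells 11 of 12 arterial genes were lower (median −0.62), with Gja5, a connexin of arteries, at −2.41 (8 against 70 UMIs), Vegfc at −1.24 and Sox17 at 0.30. Tip cell genes had a median of 0.48 with 7 of 9 higher, with Adm at 0.80, Pgf at 0.62 and Cxcr4 at −0.73, and this median was 0.10 with cells thinned to 2000 UMIs. Venous and capillary genes stood at 0.06. The endothelial extremes were Ccl21a at 2.57 (93.2% of KO UMIs in 1 cell), Mdga2 at 1.60 and Vtn at 1.33 (41.4%), and Epha3 at −3.37, Fabp7 at −3.34 and Galntl6 at −2.7001, whose WT UMIs lie to 73.8%, 82.3% and 82.4% in 1 cell. With cells thinned, Epha3 turned to 0.37 and Galntl6 to 0.

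Across the 5 standardised classes the genes furthest above 0 in N123 KO were Sema3d at 0.86 (0.74 to 0.97), Sncg at 0.81 (0.67 to 0.94), Prph at 0.78, Hand2 at 0.78 (0.69 to 0.88), Prr16 at 0.73, Ptprt at 0.71, Cadm1 at 0.69 and Dlgap1 at 0.64. Prph rests largely on neuron-like cells, where a single cell held a good part of its KO UMIs. Over the sum of all cells, which mixes classes of unequal share, Sncg turned to −0.45, Prph to −0.19, Ptprt to −0.25 and Cadm1 to −0.27, and as a median over classes Hand2 was at 0.076. Furthest below 0 were Fabp7, a fatty acid binding protein of neural progenitors, at −1.30 (−1.41 to −1.17), H1f5 at −1.001 (−1.09 to −0.91), Igfbpl1 at −0.99 (−1.11 to −0.89), H1f1 at −0.88, Nusap1 at −0.77, Tubb3 at −0.76, H2ac8 at −0.76 and Hes1 at −0.71. The genes of chromatin and division among them were close to 0 without doublet removal, with H1f5 at −0.17, H1f1 at −0.20, Nusap1 at −0.17 and H2ac8 at −0.20. Without doublet removal the mean was over 6 classes, which left out chondrocyte-like and added neural progenitor- and surface ectoderm-like cells. How much of such a shift comes from doublets cannot be told apart from this change of classes. Fabp7 and Tubb3 are abundant in neural cells, whose share of N123 WT was 12.3% for neural progenitor-like and 18.0% for neuron-like cells. Genes of S phase (median −0.33) and of G2 and M phase (−0.35) were lower in all 42 measured members each. Over the sum of all cells they stood at −0.024 and 0.04, and without doublet removal at −0.15 and −0.10. The 5 classes leave out unnamed cluster 2, with H2ac8, Top2a, Nusap1, H1f1 and H1f5 among its leading genes. It held 17.7% of N123 KO and 10.6% of N123 WT cells. Lower division genes in the 5 classes therefore need not mean fewer dividing cells in KO.

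The remaining lists had the following standardised medians in N123. Below 0 were proneural genes (−0.23, 14 of 16 lower), neuronal differentiation genes (−0.24), neural progenitor genes (−0.20), pericyte genes (−0.21, 9 of 9 lower), red cell genes (−0.35, 7 of 7 lower), chondrogenic genes (−0.10, and 0.14 over the sum of all cells), myogenic progenitor genes (−0.07, and 0.006 as the median over classes), glial genes (−0.05), arterial genes (−0.05), tip cell genes (−0.05), interferon response genes (−0.03), Hedgehog targets (−0.03), p53 targets (−0.01) and fibrillar matrix genes (−0.004). Above 0 were contractile genes (0.27, 9 of 10 higher), mitochondrially encoded genes (0.22), myogenic differentiation genes (0.15, but −0.01 with a pseudocount of 1 CPM), biliary genes (0.12), hypoxia and glycolysis genes (0.08), Wnt targets (0.07), hepatocyte genes (0.05), Notch ligands, receptors and machinery (0.05), dissociation and stress genes (0.04), Hes and Id genes (0.03) and venous and capillary genes (0.02).

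The Rbpj comparison asked the same of Tomato+ cells marked for deletion of the common transcriptional partner of the receptors, 2 embryonic days later. Neural shares over all kept cells were close in Rbpj KO and Rbpj WT, while endothelial-like and skeletal muscle-like cells were scarcer in KO. Neural progenitor-like cells made up 2.15% of KO and 2.24% of WT (log2 −0.06, −0.30 to 0.18), and neuron-like cells 4.18% and 3.85% (0.12, −0.06 to 0.30). Endothelial-like cells made up 2.59% of KO (2.30 to 2.91; 277 cells) and 16.6% of WT (16.0 to 17.2; 2672 cells), a log2 ratio of −2.68 (−2.86 to −2.50). Skeletal muscle-like cells made up 1.37% against 4.18% (log2 −1.60, −1.87 to −1.35). Surface ectoderm-like cells were higher, at 7.18% against 1.77% (2.02, 1.82 to 2.22), as were mesenchyme-like cells at 25.4% against 13.2% (0.95), mural-like cells at 6.93% against 3.85% (0.85, 0.69 to 1.00), chondrocyte-like cells at 4.21% against 2.37% (0.83) and mesothelium-like cells at 0.729% against 0.217% (1.75). Neural crest glia-like cells stood at 1.36% and 1.26%.

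Part of these differences lies in 9 clusters whose Rbpj cells came to over 90% from the WT library after weighting by library size. They held 5570 cells of Rbpj WT, or 34.6%, but 115 cells of Rbpj KO (1.08%), 58 of N123 KO and 46 of N123 WT, and included most hepatocyte-, cardiomyocyte- and erythroid-like cells of Rbpj WT. Cardiomyocyte-like cells, all in cluster 34, numbered 386 in WT and 9 in KO, hepatocyte-like cells stood at 4.47% against 0.440%, erythroid-like cells at 8.75% against 2.79%, other blood-like cells at 2.70% against 0.804% and macrophage-like cells at 1.452% against 1.08%. Endothelial-like cells lay mostly in cluster 14 in KO (82.3%) and in cluster 7 in WT (56.8%), and cluster 7 is one of the 9. Without the 9 clusters, an alternative chosen after seeing the data, endothelial-like shares were 2.25% against 6.78% (log2 −1.59, −1.81 to −1.38), skeletal muscle-like shares at −1.69, surface ectoderm-like at 1.42, neural progenitor-like at −0.65, neuron-like at −0.13 and glia-like at 1.37% against 1.92% (−0.49, −0.81 to −0.17). The higher shares in KO were then at 0.35 for mesenchyme-like, 0.25 for mural-like (0.11 over all clusters with classes from marker scores), 0.23 for chondrocyte-like and 1.15 for mesothelium-like cells. The lower ones were at −0.25 for erythroid-like (2.65% against 3.14%), −0.44 for other blood-like, −1.02 for macrophage-like and −1.85 for hepatocyte-like cells. Kept Rbpj WT cells were shallower than those of KO, with medians of 6765 and 10533 UMIs. The share of filtered barcodes removed as doublets, 15.2% in WT and 9.45% in KO, was set by the number of barcodes and measures no difference in doublets. Osteoblast-like cells stood at 0.739% against 1.31% and peripheral neuron-like cells at a log2 ratio of −0.64, and these turned to 0.32 and 0.47 with classes taken from the highest marker score, but stood at −1.42 and −1.23 without the 9 clusters.

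Notch target genes had a standardised median of −0.16 in Rbpj KO, with 6 of 9 members lower and 0.52% of matched random lists below it. It was −0.085 as the median over classes, −0.39 over the sum of all cells and −0.42 with a pseudocount of 1 CPM. Hes1 was at −0.77 (−0.86 to −0.69), Hes5 at −0.57 (−0.72 to −0.43), Nrarp at −0.48, Heyl at −0.32 and Hey2 at −0.12, whereas Hey1 was at 0.42 (0.28 to 0.56) and turned to −0.15 over the sum of all cells. Without the 9 clusters Hes1 was at −0.57, Hes5 at −0.45 and Nrarp at −0.26. By class the median was −0.71 in neural crest glia-like, −0.55 in surface ectoderm-like, −0.51 in mural-like, −0.42 in neural progenitor-like, −0.10 in endothelial-like, −0.03 in mesenchyme-like, −0.01 in skeletal muscle-like and 0.36 in neuron-like cells. Of the neural progenitor-like clusters, cluster 12 stood at −0.52 (6 of 7 lower) and cluster 25 at 0.08 (3 of 5 higher). Without the 9 clusters the median was −0.13 in endothelial-like, −0.096 in skeletal muscle-like and 0.19 in neuron-like cells. Hes1 in surface ectoderm-like cells was at −1.05, and in mural-like cells Nrarp was at −1.32 and Heyl at −1.26. In neural progenitor-like cells Hes5 had 699.9 CPM in KO and 938 CPM in WT. With cells thinned to 2000 UMIs the median was −0.069 in neural progenitor-like and −0.93 in mural-like cells, and without cells holding a PhiYFP UMI it was −0.45 in skeletal muscle-like cells. Without those cells the standardised ratio of Hes1 was −1.35 over 4 classes, which leave out skeletal muscle-like cells, and its mean over the 5 classes was −1.17.

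PhiYFP, a yellow fluorescent protein among the counted transgenes, was also read in the Tomato+ library, at 63.4 CPM in Rbpj KO against 154 CPM in Rbpj WT, with a UMI in 22.0% and 49.8% of cells. In the 5 standardised classes 967 Rbpj KO cells held a PhiYFP UMI and 3535 held none. Rbpj in the cells with a PhiYFP UMI was higher by a mean log2 difference of 0.67 (0.54 to 0.82), and without these cells, an alternative chosen after seeing the data, the standardised ratio of Rbpj was −1.23. In mesenchyme-like cells Rbpj had 32.9 CPM in KO cells with no PhiYFP UMI, 67.6 CPM in those with one and 102 CPM in WT, and Hes1 had 71.8, 212 and 180.1 CPM. The log2 difference in Rbpj was highest there (0.94) and lowest in skeletal muscle-like cells, at 0.17 (−0.19 to 0.55; 73.4, 83.4 and 127 CPM), and Hes1 in neuron-like cells had 4.16, 6.57 and 26.9 CPM. No such split exists for N123, where PhiYFP, although a listed feature, had 0 UMIs in both libraries (limits of 0.0313% of KO and 0.0324% of WT cells). Whether the YFP of that experiment is PhiYFP is not given in the sources used here, so this 0 is no measure of cells bearing YFP.

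**Figure D3:**
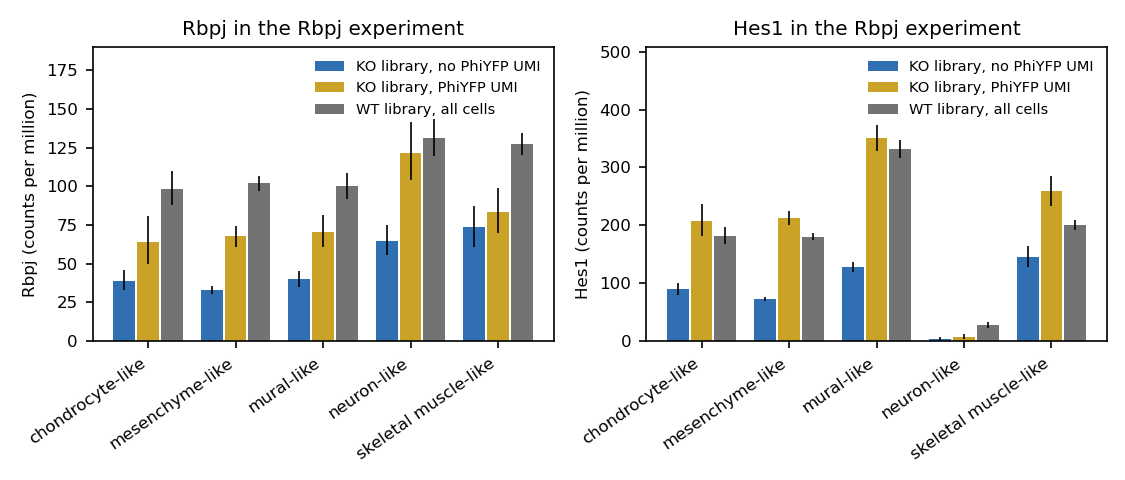
CPM of Rbpj and Hes1 (bars, y axes) by class in Rbpj KO cells without and with a PhiYFP UMI and in Rbpj WT cells, with Poisson intervals as error bars. In mesenchyme-like cells Rbpj is 32.9, 67.6 and 102 CPM in that order.

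Pericyte genes were lower in the mural-like cells of Rbpj KO, as they were in N123 KO. All 9 members were below 0, with a median of −0.82, among them Rgs5, a regulator of G-protein signalling abundant in pericytes, at −1.61 (86.8 against 276 CPM), Vtn at −1.56 and Anpep at −0.17. The median was −1.58 without the cells that held a PhiYFP UMI and −1.25 with cells thinned to 2000 UMIs. Contractile genes in the same cells stood at −0.04 (Tagln −0.54, Myh11 0.18). Within clusters 26, 16 and 23 pericyte genes had medians of −0.98, −0.78 and −0.35 and contractile genes of −1.17, −0.34 and 0.54. The other mural extremes were Lix1 at 1.13, Kctd14 at 1.06 and Adamts19 at 1.05, with Fabp7 at −1.86. The most numerous cluster of mural-like cells was cluster 16 in KO, with 39.4% of them, and cluster 26 in WT, with 36.1%.

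Skeletal muscle-like cells of Rbpj KO lacked the uniform difference of N123 KO. Their myogenic differentiation genes had a median of 0.05, with 7 of 13 higher (Mymx 0.85, Myog 0.77, Myh8 −1.04, Myh3 −0.85), which was −0.22 without the 9 clusters and 0.69 without cells holding a PhiYFP UMI, and progenitor genes stood at −0.10 (Met −0.51), at −0.26 without the 9 clusters and at 0.11 with cells thinned to 2000 UMIs. Car3 was at 2.34 there, while Myh11 at 3.40 and Actg2 at 2.41 had 99.6% and 94.8% of their KO UMIs in 1 cell, and without cells holding a PhiYFP UMI they turned to −0.41 and −0.32. The endothelial genes Cldn5 at −4.51, Cdh5 at −3.88 and Kdr at −3.74 were the lowest in this class. They stood at −0.73, −0.49 and −0.72 without the 9 clusters, 1 of which, cluster 46, was named skeletal muscle-like with endothelial genes next.

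Neural progenitor-like cells of Rbpj KO had lower progenitor genes, with 12 of 13 below 0 (median −0.51; Ptprz1 −0.84, Fabp7 −0.68). In this class, which holds none of the 9 clusters, fibrillar matrix genes had a median of 0.56 with 12 of 15 higher. The median doublet score was 0.051 in KO and 0.041 in WT in cluster 12, and 0.046 in each in cluster 25. Proneural genes in the same cells stood at −0.04 (Neurod4 1.32) and neuronal differentiation genes at 0.18 with 13 of 15 higher. Extremes there were Atoh7 at 4.56 (457 against 7 UMIs, 31.1% of the KO UMIs in 1 cell), Vtn at 2.08 (81.9% of KO UMIs in 1 cell), Crybb1 at 2.01 (96.4%), Cck at −2.59 (0 against 78 UMIs, 47.4% of these in 1 WT cell), Neurog3 at −2.23 (69.0% of WT UMIs in 1 cell) and Ulk4 at −1.63. Crybb1 and Neurog3 turned to −0.24 and 0.46 at the lower clustering resolution. In neuron-like cells, whose most numerous cluster was cluster 35 in KO (30.9%) and cluster 9 in WT (27.4%), proneural genes stood at 0.12 (−0.04 without doublet removal) and neuronal differentiation genes at 0.001 (Tubb3 0.33, Nefl −1.15). Pmch at 5.10 came from 667 UMIs of 1 cell and Olfr1122 at −4.56 from 0 against 398 UMIs with 67.6% in 1 WT cell, and Six6 was at 1.84 (30.6% of KO UMIs in 1 cell), Ttr at 1.83 (85.9%, and −0.19 without doublet removal), Anxa2 at −2.84 (−0.50 without the 9 clusters) and Sncg at −2.80 (1.47 without them).

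Of endothelial-like cells, 63.2% in Rbpj KO and 64.7% in Rbpj WT held a PhiYFP UMI (32.5% and 33.1% at 2000 UMIs). In endothelial-like cells of Rbpj KO venous and capillary genes had a median of 0.41 with 8 of 9 higher (Vwf 0.91, Emcn 0.84, Nr2f2 −0.18). Without the 9 clusters this median was 0.05 with 5 of 9 higher. Vwf, with 38.1% of its KO UMIs in 1 cell, turned to −0.31 at a limit of 5% mitochondrial UMIs. Arterial genes stood at 0.09 (Sox17 0.51, Fbln5 −1.56), which turned to −0.30 without the 9 clusters and to −0.32 without cells holding a PhiYFP UMI, and tip cell genes at 0.33, which was 0.02 without the 9 clusters. Lists of other cell types were also below 0 in this class without the 9 clusters. Pericyte genes stood at −0.64 (8 of 8 lower), fibrillar matrix genes at −0.41 (13 of 15) and contractile genes at −0.31 (7 of 7). Madcam1 was at 0.94 and Fam89a at 0.91, against 0.39 and 0.56 without the 9 clusters. Fabp7 at −3.74, Col1a1 at −3.55 and Ttr at −3.51 were lowest, and stood at −1.42, −0.97 and −0.81 without them. Notch2 in this class had 3.55 CPM in KO against 39.5 CPM in WT, and 3.03 against 7.48 CPM without them (log2 −0.64).

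**Figure D4:**
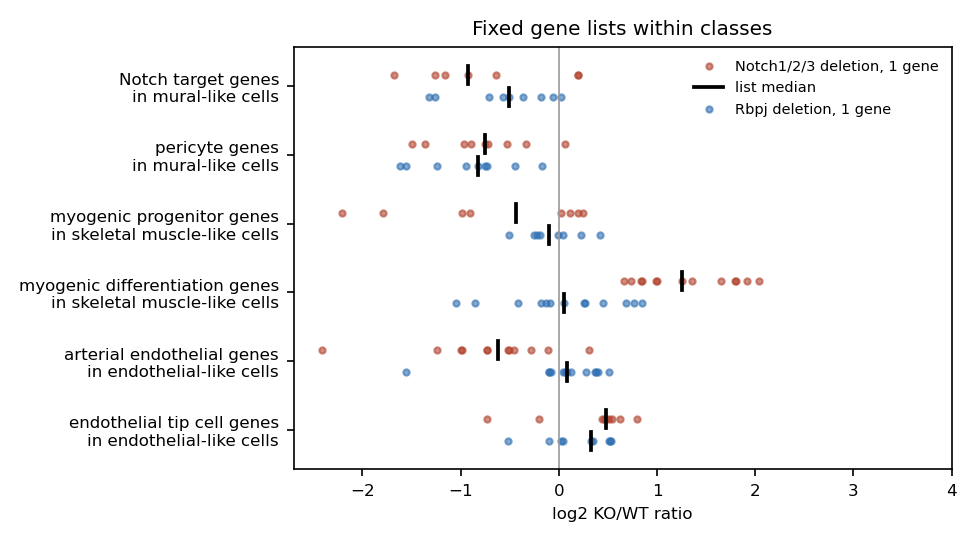
Log2 KO/WT ratio (x axis) of each measured member of fixed gene lists within classes (y axis), with 1 point per gene for the Notch1/2/3 deletion and the Rbpj deletion and a black bar at each list's median. Pericyte genes in mural-like cells have medians of −0.75 in N123 and −0.82 in Rbpj, and myogenic differentiation genes in skeletal muscle-like cells 1.26 and 0.05.

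Across the 5 standardised classes in the Rbpj experiment, Myh11 at 0.78, Lgmn at 0.57 (0.46 to 0.70), H2ac24 at 0.53 (0.41 to 0.66, but 0.095 with cells thinned), Hoxc10 at 0.42, Cnn1 at 0.39, Isl1 at 0.39, Dpysl4 at 0.39 and Pla2g12a at 0.37 lay highest. Myh11 rests largely on skeletal muscle-like cells, where nearly all of its KO UMIs lay in a single cell. Lowest were the endothelial genes Cldn5 at −1.86, Cdh5 at −1.38, Ecscr at −1.37 and Emcn at −1.25, then Fabp7 at −1.35 (−1.46 to −1.25), Ulk4 at −1.30 (−1.43 to −1.18), Sncg at −1.08 and Igfbp7 at −1.03. Without the 9 clusters Cldn5 was at −0.67, Cdh5 at −0.37, Ecscr at −0.56, Emcn at −0.33, Igfbp7 at −0.32, Sncg at −0.03 and Myh11 at 0.11, Cnn1 turned to −0.005, and Fabp7 and Ulk4 stayed at −1.10 and −1.29. Fabp7 was thus low in KO in both experiments, at −1.30 and −1.35.

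Most other lists were below 0 in Rbpj KO. Red cell genes were at −2.36, chondrogenic genes at −0.51 (12 of 12 lower), pericyte genes at −0.47 (9 of 9), fibrillar matrix genes at −0.43 (15 of 15), venous and capillary genes at −0.39 (9 of 9) and arterial genes at −0.33 (13 of 13). Without the 9 clusters these stood at −1.43, −0.074, −0.30, −0.048, −0.12 and −0.064 in that order. The standardised muscle and neuron classes include clusters 46 and 50 of the 9, whose Rbpj WT cells held 4.28 and 2.35 Cldn5, 6.24 and 0.778 Hba-x, and 2.01 and 2.26 Col2a1 UMIs per 10000 UMIs. Neural progenitor genes and dissociation and stress genes were both at −0.24 (−0.15 and 0 without the 9 clusters), biliary genes at −0.21, myogenic differentiation and tip cell genes at −0.14, hepatocyte genes and genes of G2 and M phase at −0.13, S phase genes at −0.12, interferon response and myogenic progenitor genes at −0.11, Hedgehog targets and Hes and Id genes at −0.09, neuronal differentiation genes at −0.08, contractile genes at −0.07, Notch ligands, receptors and machinery at −0.06, Wnt targets at −0.03, and proneural and glial genes at −0.01. Mitochondrially encoded genes were at 0.14, p53 targets at 0.04 and hypoxia and glycolysis genes at 0.01. Over the sum of all cells fibrillar matrix genes turned to 0.21, chondrogenic genes were at −0.0036 and red cell genes at −0.46, dissociation and stress genes to 0.17, neuronal differentiation genes to 0.12, Hes and Id genes to 0.06 and biliary genes to 0.03.

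Set side by side, both KO libraries had a median of Notch target genes below 0 (8 of 9 members lower in N123 and 6 of 9 in Rbpj), lower pericyte genes in mural-like cells, fewer skeletal muscle-like cells and more surface ectoderm-like and mesenchyme-like cells than their WT libraries (mesenchyme-like at a log2 ratio of 0.35 in Rbpj without the 9 clusters). The KO/WT ratios of neural and endothelial-like shares differed between the experiments. Without the 9 clusters neural progenitor-like shares in Rbpj were at −0.65, on the same side of 0 as in N123. Endothelial-like shares were 2.11% of N123 KO and 2.59% of Rbpj KO, but 0.832% of N123 WT and 16.6% of Rbpj WT. In N123 the lower muscle share lay in cluster 21 (log2 −2.39) and not in cluster 45 (0.38, −0.16 to 0.93). Across 6005 genes the standardised log2 ratios of N123 and Rbpj had a Pearson correlation of 0.079 (0.058 to 0.084) and a Spearman correlation of 0.072, and 52.6% of the genes had the same sign. This correlation is across genes, which are not independent replicates. It was 0.230 without the 9 clusters, 0.027 over the sum of all cells and −0.017 among genes with a mean of at least 100 CPM. No control library is shared between the experiments. Which deletion and which induction day a difference between them goes with cannot be told apart.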

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

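Tests chosen after the results were seen were those of free PhiYFP RNA, of free RNA, doublets and loss in the clusters nearly confined to Rbpj WT, and of removed barcodes, a shared Tomato effect and trunk cells for neural shares, and the settings without PhiYFP cells and without those clusters.

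PhiYFP is a signal outside the compared genes, at 63.4 CPM in the Tomato+ Rbpj KO library against 154 CPM in Rbpj WT, and its 0 UMIs in both N123 libraries are no measure of YFP there, as that experiment's YFP is not given in the sources used here. Free PhiYFP RNA in every droplet is argued against as the whole source, because the share of Rbpj KO cells with a PhiYFP UMI differed between classes. At 2000 UMIs it was 12.8 times as high in endothelial-like cells (32.5%, unthinned 63.2%, median 13669 UMIs, 0 cells left out) as in osteoblast-like cells (2.53%, 0.31 to 8.85, unthinned 13.9%, median 15005 UMIs, 0 left out), the highest and lowest class. In endothelial-like cells of Rbpj WT the share was 33.1% (unthinned 64.7%), close to that of KO. Deleted cells that also carry PhiYFP are argued against as the whole source, since Rbpj was higher in cells with a PhiYFP UMI by a mean log2 difference of 0.67, where deleted cells would show none. WT cells bearing PhiYFP among the sorted Tomato+ cells may therefore account for part of the Rbpj and Hes1 transcripts in this library, as a hypothesis, and the difference of 0.67 is what it needs. Against a complete account, Ulk4 and Notch2, chosen after their values were seen, stood at log2 ratios of −1.25 and −0.91 against Rbpj WT in the cells with a PhiYFP UMI, and doublets of a Tomato+ and a YFP+ cell were not tested.

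The 9 clusters nearly confined to Rbpj WT held 34.6% of its cells and 1.08% of Rbpj KO. A single pool of free RNA over the library is argued against, as Hba-x per 10000 UMIs was 320-fold higher (211 to 511) in the endothelial-like cells of these clusters than in the other endothelial-like cells of the same library. Doublets, and free RNA in part of the droplets, stay open, because the median UMI count of these cells was 0.516 of that of the other cells but their median doublet score was higher (0.056 against 0.042), and clusters 46, 34 and 27, named for muscle, heart and liver, held 4.28, 3.03 and 2.65 Cldn5 UMIs per 10000 UMIs against 0.043 in muscle cluster 21. Loss of such cells after deletion of Rbpj cannot be told apart from a difference in embryos or tissue between the sorted samples, because these clusters made up 0.497% of N123 WT, whose induction day differs. A difference in the embryos collected was not tested.

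Neural progenitor-like and neuron-like cells were scarce in N123 KO. Removal by the filters is argued against as the whole cause. From N123 KO 1202 barcodes were removed, while 2687 neural cells were missing there against the N123 WT shares. An effect of the Tomato sort or of recombination shared by both experiments stays open. The neural progenitor-like log2 ratio in Rbpj was −0.058, and −0.65 without the 9 clusters. This ratio cannot decide, because 43.9% of these Rbpj KO cells held a PhiYFP UMI, against 53.5% in Rbpj WT (15.7% and 21.2% at 2000 UMIs). WT cells among them could hide such an effect. A lower share of head cells is argued against as the whole cause, since neural cells with at least 2 UMIs of Hox groups 6 to 13, genes of the trunk, at 2000 UMIs were scarce as well, with 51 in N123 KO and 709 in N123 WT (log2 ratio of their shares −3.85, −4.29 to −3.44; 0 and 87 neural cells left out). As part of the cause it stays open, since mesenchyme-, chondrocyte- and mural-like cells with no Hox UMI at 2000 UMIs had a share ratio of 0.999 (0.90 to 1.11; 7 and 21 cells left out), but the bound of 0.8 set before the test decides nothing, as a KO sample with no head cells would give no less than 0.839. A loss of neural cells after deletion of the receptors stays open too, together with the embryos pooled, and neither was tested. Induction day was E7.5 in both N123 libraries and so cannot account for a difference between them.

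Endothelial-like shares differed between the experiments, with log2 ratios of 1.34 in N123 and −2.68 in Rbpj, and this difference was not tested. Hey1 stood at −0.60 in N123 and 0.42 in Rbpj, and this difference was not tested either. Sncg stood at 0.81 in N123 and −1.08 in Rbpj, also untested, and at −0.03 in Rbpj without the 9 clusters.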

How the results depend on the processing

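The alternatives without PhiYFP cells and without the 9 clusters of 1 Rbpj library were chosen after seeing the data. No paired analysis was possible because each group has 1 library and no result comes from a test. Of 134 alternatives of the 17 main results 98 stayed within counting error, 34 moved and 2 turned direction from an interval without 0, and of 2090 alternatives of 209 other results 1368, 671 and 51. Whatever the interval, 6 and 116 lay on the other side of 0, and Rbpj neural progenitor- and neuron-like shares kept their side in 5 of 7 each. Notch1 in N123 stayed below 0 in 10 of 10 alternatives (−2.28 to −1.40), Rbpj in 12 of 12 (−1.23 to −0.81), Notch targets in 11 of 11 in N123 (−0.69 to −0.26) and 13 of 13 in Rbpj (−0.42 to −0.085). N123 shares kept their direction in 6 of 6 for neural progenitor- (−3.86 to −3.61), neuron- (−3.81 to −3.08), muscle- (−1.46 to −0.97), ectoderm- (0.84 to 1.00) and endothelial-like cells (1.31 to 1.48). Shallow Rbpj WT cells limit what thinning can show there. The classes standardised vary by setting. Unless the setting's own construction removes cells or clusters, the cause was not tested. The stricter UMI filter, median-of-ratios scaling and no low-count filter moved none of the main results. Values below are log2 ratios.

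Resolution 0.5 gave neuron-like 0.44 and endothelial-like shares −2.21 in Rbpj and N123 Notch targets −0.63, and turned in Rbpj peripheral neuron-like share to 0.54, Crybb1 to −0.24, Neurog3 to 0.46, Olfr1122 to 0, neuron Sncg to 1.49 and neuron proneural genes to −0.13. Resolution 2.0 gave N123 neuron-like share −3.43 and Rbpj endothelial-like share −2.09, and turned Rbpj osteoblast-like share to 0.29. At 5% mitochondrial UMIs Rbpj shares were 0.36 for neuron-, −3.40 for endothelial- and −1.21 for muscle-like cells, and Crybb1 turned to −0.12, Vwf to −0.31 and endothelial arterial genes to −0.17. Marker scores gave N123 shares of −3.08 for neuron- and −0.97 for muscle-like cells and Rbpj shares of −0.67 for neural progenitor-, −0.064 for neuron-, −1.84 for endothelial-, −1.185 for muscle- and 1.355 for ectoderm-like cells, and turned peripheral neuron-like to 0.28 in N123 and 0.47 in Rbpj and osteoblast-like in Rbpj to 0.32.

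Thinning gave N123 Notch targets −0.66, Notch2 −0.34 and Notch3 −0.81 and Rbpj −1.004, and turned Epha3 to 0.37, Galntl6 to 0 and Notch3 in Rbpj to 0.11. At 100 CPM the correlation between experiments turned to −0.017. The median over classes gave N123 Notch targets −0.26 and myogenic progenitor genes 0.0059. Without doublet removal Rbpj endothelial-like share was −2.01 and Rbpj −0.81. It turned in N123 neurons H1f5 to 0.25 and Top2a to 0.27, and in Rbpj macrophage-like share to 0.046, neuronal differentiation genes to 0.0073, fibrillar genes to 0.033, neuron Ttr to −0.19, neuron Sncg to 0.71, endothelial Ttr to 0.45, endothelial arterial genes to −0.066 and neuron proneural genes to −0.039. A pseudocount of 1 CPM gave Notch targets −0.69 in N123 and −0.42 in Rbpj and Notch1 −2.28, and turned N123 myogenic differentiation genes to −0.014.

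The sum over all cells gave N123 Notch1 −1.90, Rbpj Notch targets −0.39 and a correlation of 0.027. In N123 it turned Notch2 to 0.0025, chondrogenic genes to 0.14, G2 and M phase genes to 0.043, Sncg to −0.45, Prph to −0.19, Ptprt to −0.25, Cadm1 to −0.27 and H2ac8 to 0.0082, and in Rbpj neuronal differentiation genes to 0.12, fibrillar to 0.21, biliary to 0.035, stress to 0.17, Hes and Id genes to 0.060 and Hey1 to −0.15. Without PhiYFP cells Rbpj was −1.23 over 4 classes (−1.13 over the 5), Pmch turned to 0, muscle Myh11 to −0.41, muscle Actg2 to −0.32 and endothelial arterial genes to −0.32. Without the 9 clusters Rbpj shares were −0.65 for neural progenitor-, −0.13 for neuron-, −1.59 for endothelial- and 1.42 for ectoderm-like cells and the correlation 0.230, and neuronal differentiation genes turned to 0.011, Hes and Id genes to 0.044, Cnn1 to −0.0053, neuron Sncg to 1.47, endothelial arterial genes to −0.30 and neuron proneural genes to −0.0085.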

Other observations

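No test was run for the values of this part, which were all chosen after the results were seen, except for the gene lists, which were fixed before the data were examined.

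Caudal mesenchyme and specialised endothelium stood out among the clusters with no name. Cluster 18, led by Hoxc13, Hoxc12, Pax1, Pax9 and Hoxb13, genes of the posterior body axis and of somite derivatives, held 566 cells of N123 KO and 182 of N123 WT, and 93 cells of Rbpj KO and 23 of Rbpj WT. Cluster 37, with Hoxc13, Hoxc12 and Hoxb13 among its leading genes as well, held 280 cells of Rbpj KO and 53 of Rbpj WT. After weighting by library size 75.0% of the N123 cells and 85.9% of the Rbpj cells of cluster 18 came from the KO library. Cluster 33, led by Lyve1, Stab2 and Oit3, genes of liver sinusoidal and lymphatic endothelium, held 85 cells of N123 KO, 8 of N123 WT, 130 of Rbpj KO and 197 of Rbpj WT. Its best candidate name was endothelial-like, but no marker of that name was among its top 20 genes. The endothelial-like shares given above therefore leave it out.

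Cell division genes went different ways in different classes. In N123 KO, S phase genes had a median of 0.33 with 41 of 42 higher in surface ectoderm-like cells and 0.24 with 35 of 42 higher in endothelial-like cells, against −0.43 with 42 of 42 lower in neural progenitor-like cells. In Rbpj KO, genes of G2 and M phase had a median of 0.26 with 40 of 42 higher in surface ectoderm-like cells. Chondrogenic genes in chondrocyte-like cells had a median of −0.27 in N123 KO with 12 of 12 lower, among them Matn1 at −0.55 and Acan, the main proteoglycan of cartilage, at −0.54. In Rbpj KO 10 of 12 were lower there. The class is not made of like cells in the experiments. In N123 KO 99.0% of it lay in cluster 1, which shares leading genes with mesenchyme-like cluster 0, and in Rbpj KO 100% lay in cluster 19.

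Ulk4 (GRCm39 chromosome 9, 120784417 to 121106263) was lower in Rbpj KO in all 5 standardised classes, with a mean of −1.30, while its 19 measured neighbours within 1000000 bp had a median of −0.01 and lay between −0.21 and 0.18. The Cdh5-CreERT2 transgene feature was read in all 4 libraries, at 11.6 CPM in N123 KO, 11.0 CPM in N123 WT, 59.3 CPM in Rbpj KO and 61.1 CPM in Rbpj WT, and the WPRE feature at 350.4, 489, 1052 and 1371 CPM. The Cdh5-CreERT2 feature had a UMI in 14.9%, 13.6%, 45.1% and 33.6% of cells in that order, while endothelial-like cells were 2.59% of Rbpj KO. Whether these reads come from that transgene was not tested. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d summed to 0.268, 0.264, 0.232 and 0.2503 CPM in the same order.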
